A study of Homo sapiens with 9 samples.

How the data were processed

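Small RNA libraries of 9 samples of Jurkat clone E6-1 were analysed: unactivated cells (0 h) and cells activated with antibodies to CD3 and CD28 for 5 h and 12 h, with 3 biological replicates at each time. Per the labels, total RNA was extracted with a column kit and the libraries were made with RealSeq kits. The authors also made mRNA and ribosome profiling libraries, which are not analysed here.

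The authors deposited a table of raw counts per library, with 1 row for each pair of miRNA precursor and mature miRNA (2883 rows, 2654 distinct mature names and 1917 precursors). Per the labels, the genome build was GRCh38.p13 and DESeq2 was used by the authors; the aligner, the counting tool and the version of DESeq2 are not given in the sources used here. For many mature miRNAs with several precursors, nearly the same count appears again on each precursor row, but not for all. In total, 165 mature miRNAs have 2 or more precursor rows. Of 41 such miRNAs with at least 200 counts, 27 have rows within 5% of each other. The median ratio of the lowest to the highest row is 99.4%, and the smallest is 14.8%. The authors also deposited a table of log2 normalised values. Its 430 rows (378 mature miRNAs) are the 430 count rows above 0 in all 9 libraries, and its values equal log2 of (count divided by 1 factor per library, plus 1) to within 5.05e-09. The log2 table lacks 272 of the rows tested here, including both arms of miR-212, and was used only in an alternative.

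Groups and replicates were taken from the sample labels, which name no batch, date or pairing. Of 1214 rows above 0 in any library, 701 passed filterByExpr in edgeR (minimum count 10, minimum total 15). They cover 626 mature miRNAs and 99.99% of the counts. Counts were scaled by TMM and modelled in edgeR 4.0.16 (R 4.3.3) with a quasi-likelihood fit of 1 mean per time over all 9 libraries. Contrasts compared 5 h with 0 h, 12 h with 0 h and 12 h with 5 h, and an F test asked for any difference among the 3 times. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the rows of each comparison. Log2 fold changes are those of the fit, with the SE derived from its test. CPM are counts per 1000000 counts of the table after TMM scaling, so repeated precursor rows enter the total. For a miRNA with 0 counts in a whole group, the fold was computed against 3 counts over that group.

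Total table counts ranged from 6631839 to 16207031 per library, or 4232272 to 10450005 with each mature miRNA counted once. A count of 3 corresponds to 0.176 CPM in the deepest and 0.471 CPM in the shallowest library. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. The common biological coefficient of variation was 77.0% over all tested rows, most of which have low counts.

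In all, 29 lists of miRNAs were fixed before the data were examined, together with the test, the filter, the alternatives and the rule for which miRNAs are named. They cover miRNAs reported to change in T cell activation, NF-kB-linked miRNAs, clusters and families, other cell types and entries that match structured RNAs. The 23 lists with 3 or more tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Camera with an estimated correlation and fry were the alternatives. Counts of members in a list took each mature name once, whereas camera and fry took every tested row, repeated precursor rows included. The naming rule took, for each time against 0 h, up to 10 miRNAs that rose and 10 that fell among those past the threshold, with groups that did not overlap and a mean of at least 10 CPM. For 12 h against 5 h it took up to 5 each. It added 18 miRNAs of interest in T cells, the 5 most abundant miRNAs and up to 4 members of each list that passed. miR-122-5p, miR-210-3p, miR-451a, let-7b-5p, let-7d-5p, let-7i-5p and miR-26a-5p were named after their values were seen.

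The share of the 10 most abundant miRNAs was compared by exact two-sided permutation tests with each mature miRNA counted once. Ratios of the 2 arms of a precursor were tested with limma. Replicates were checked for duplicated libraries, and none were found: the chi-square over degrees of freedom between replicates was 77.2 or more. The correlation of the 5 h and 12 h changes was set against 100 simulations in which the groups did not differ. Genome positions come from GENCODE 29 on GRCh38. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

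The alternatives were other scalings (library totals, RLE and upper quartile factors), no filter or a stricter filter (10 CPM in 3 libraries), DESeq2 1.42.0 and limma-voom. Others were only the 2 groups compared, the replicate number as a block, no entries matching structured RNAs, limma on the deposited log2 values, and each library left out in turn. Using 1 row per mature miRNA and leaving out the 2 shallowest libraries were added after the data were seen.

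The fit was tested on simulated data with planted changes, at the depth and spread of these libraries. The rows changed 1.5-fold, 2-fold and 4-fold were 63, 57 and 60 of 616 tested for 5 h, and 58, 57 and 64 of 613 for 12 h. These are many more than were called in the real data, which makes the adjusted threshold less strict. The shares recovered may therefore be too high for the real data, and they leave out rows removed by the filter. For 5 h against 0 h, edgeR recovered 17.5%, 36.8% and 55% of rows changed 1.5-fold, 2-fold and 4-fold, and 57.1%, 100% and 100% of those with a mean of at least 100 CPM. Of its calls, 2.99% were unchanged rows. For 12 h against 0 h it recovered 20.7%, 29.8% and 62.5%, and 58.8%, 100% and 100% of abundant rows, and 8% of its calls were unchanged rows. A change planted in the let-7 list was called by camera.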

Results

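Small RNA was sequenced from Jurkat clone E6-1, an established human T lymphoblast line used as a model of T cell receptor signalling. Cells were collected before activation (0 h) and 5 h and 12 h after the start of activation. Activation used plate-bound antibody to CD3, the signalling part of the T cell receptor (10 µg/mL), with soluble antibody to the costimulatory receptor CD28 (5 µg/mL). Each time had 3 biological replicates, which made 9 libraries, and the 0 h cells served as the background for every value at 5 h and 12 h. No unactivated cells were sampled at 5 h or 12 h. Effects of activation therefore cannot be told apart from those of time in culture or handling. The total counts of replicates 1, 2 and 3 were 15121491, 13417648 and 7083813 at 0 h. They were 10376448, 10071972 and 16207031 at 5 h, and 12620236, 11798947 and 6631839 at 12 h. Abundance is given as counts per 1000000 counts of the table (CPM), as mean ± SD over 3 libraries, and changes are log2 fold changes with their standard error (SE).

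The most abundant miRNAs were let-7a-5p, miR-191-5p, miR-16-5p, let-7f-5p and let-7g-5p. With each mature miRNA counted once, let-7a-5p held 13.8% ± 1.29 of the counts at 0 h, 13.6% ± 0.522 at 5 h and 13% ± 0.289 at 12 h (SD, n = 3). The shares over all 9 libraries were 12.2% ± 0.781 for miR-191-5p, 9.70% ± 0.658 for miR-16-5p, 7.01% ± 0.685 for let-7f-5p and 6.72% ± 0.615 for let-7g-5p. The 10 most abundant miRNAs, which also included miR-181a-5p, let-7b-5p, let-7i-5p, miR-26a-5p and let-7d-5p, held 68.7% ± 1.05 of the counts at 0 h, 67.6% ± 0.746 at 5 h and 66.9% ± 0.668 at 12 h. The differences were -1.04 percentage points at 5 h (exact two-sided permutation p = 0.2) and -1.82 points at 12 h against 0 h (exact permutation p = 0.2). The difference between 12 h and 5 h was -0.777 points (exact permutation p = 0.3), and the smallest p that 3 against 3 libraries can give is 0.1. In a principal component analysis the first component held 18.2% and the second 15.9% of the variance. Replicate 3 of 0 h (-19.4 on the first and 22.8 on the second component) and replicate 3 of 12 h (27.7 and 17.0) lay apart from the other 7 libraries, and they were also the shallowest.

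The first comparison asked which miRNAs had changed 5 h after activation. miR-132-3p, a miRNA induced by CREB signalling in many cell types, rose from 442 ± 39.9 to 3192 ± 295 CPM, a 7.22-fold increase (log2 change 2.85, SE 0.12, n = 3, edgeR adjusted p = 3.19e-12). Its opposite arm miR-132-5p rose from 4.00 ± 4.38 to 52.4 ± 3.19 CPM (log2 change 3.70, SE 0.60, adjusted p = 0.000974). miR-21-5p, a miRNA whose transcription is driven by AP-1 and STAT3, rose 2.66-fold from 255 ± 43.1 to 679 ± 32.4 CPM (log2 change 1.41, SE 0.15, adjusted p = 3.39e-06), and its opposite arm miR-21-3p rose 18.1-fold from 4.81 ± 3.19 to 84.2 ± 7.19 CPM (log2 change 4.18, SE 0.43, adjusted p = 3.39e-06). miR-146a-5p, a target of NF-kB that represses the signalling adaptors TRAF6 and IRAK1, rose from 255 ± 8.91 to 478 ± 31.4 CPM (log2 change 0.90, SE 0.13, adjusted p = 0.000159). A single miRNA fell: miR-4521, a miRBase entry that has been reclassified as a fragment of a precursor tRNA, went from 275 ± 41.7 to 83.2 ± 8.06 CPM (log2 change -1.72, SE 0.19, adjusted p = 4.71e-06).

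Both arms of miR-212, which is encoded beside miR-132, were near the detection limit before activation. miR-212-3p rose from 0.386 ± 0.668 CPM, with counts of 18, 0 and 0 in the control replicates, to 11.4 ± 1.64 CPM at 5 h (adjusted p = 0.00545). Without replicate 1 of 0 h the controls held 0 counts of miR-212-3p, and the fitted log2 change went from 4.65 to 9.99, a value that depends on the prior count and is no bound. Without replicate 2 of 0 h it was 4.04. miR-212-5p had 0 counts in all 3 control libraries and 5.08 ± 4.29 CPM at 5 h, at least 59.6-fold higher than the level of 3 counts over the control group (0.0852 CPM; adjusted p = 0.00129). That limit was 31.3-fold without replicate 1 of 5 h, and 33.2-fold and 37.4-fold without replicate 1 and 2 of 0 h. The miR-212-5p call was lost with limma-voom (adjusted p = 0.0501), where the fitted log2 change was 6.47 in place of 8.88, values that depend on the prior count as well. The miR-132-5p change was 5.23 without replicate 2 of 0 h, which held 116 of that arm's counts against 6 and 18 in the other controls, and 4.83 with limma-voom. On the deposited log2 values, with limma, the miR-132-5p call was lost (log2 change 4.48, adjusted p = 0.0763).

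For 3 smaller increases at 5 h the adjusted p crossed the threshold without single libraries or under other settings, while the changes stayed positive. miR-222-5p rose from 71.4 ± 25.4 to 158 ± 14 CPM (log2 change 1.15, SE 0.25, adjusted p = 0.0191) and miR-222-3p, a repressor of the cell cycle inhibitor p27, from 717 ± 42.0 to 1011 ± 51.6 CPM (log2 change 0.49, SE 0.11, adjusted p = 0.0230). miR-92a-1-5p, the less abundant arm of a member of the miR-17/miR-92a cluster, rose from 68.0 ± 13.9 to 132 ± 20.5 CPM (log2 change 0.96, SE 0.21, adjusted p = 0.0181). The miR-222-3p call was lost without replicate 1 (adjusted p = 0.0820) or replicate 3 of 0 h (0.122) and without replicate 1 (0.504), 2 (0.314) or 3 of 5 h (0.175), as well as with no filter on low counts (0.0625). The miR-222-5p call was lost without replicate 2 of 0 h (adjusted p = 0.0750), replicate 1 of 5 h (0.0630) or replicate 2 of 12 h (0.0948), and with a stricter filter (0.0712). The miR-92a-1-5p call was lost without replicate 3 of 0 h (adjusted p = 0.101), replicate 2 of 5 h (0.314) or replicate 3 of 5 h (0.0628). With limma on the deposited log2 values all 3 were lost, with an adjusted p of 0.279 for miR-222-3p and miR-222-5p and 0.155 for miR-92a-1-5p. Where the calls were lost, the log2 change was 0.41 to 0.51 for miR-222-3p, 0.84 to 1.18 for miR-222-5p and 0.77 to 0.97 for miR-92a-1-5p.

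In all, 11 of 701 tested rows passed at 5 h, 10 of them higher and 1 lower than at 0 h. With no filter on low counts 17 passed, 10 higher and 7 lower, and limma on the deposited log2 values called 5. Without replicate 2 of 5 h the split was 9 higher and 2 lower. In 76 rows (10.8%), among them the 11 that passed, the 3 values of one group all lay on one side of the 3 of the other, against 10% by chance. Among 139 rows with a mean of at least 100 CPM, 5 passed, and the largest change among the others was 0.51 in size.

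miR-155-5p, a miRNA processed from the BIC transcript that rises in activated primary lymphocytes, had 2.71 ± 2.85 CPM at 0 h, 9.37 ± 1.38 at 5 h and 9.36 ± 2.97 at 12 h, and did not pass at either time (log2 change 1.84, SE 0.67, at both; edgeR adjusted p = 0.538 and 0.511). Without replicate 3 of 0 h, which held 5.94 CPM against 0.579 and 1.61 in the other controls, it passed at 5 h (log2 change 3.09, adjusted p = 0.0101) and at 12 h (3.10, adjusted p = 0.0111). It also passed without the 2 shallowest libraries, replicate 3 of 0 h and of 12 h (adjusted p = 0.0296 and 0.0393). miR-221-3p had 422 ± 55.8, 582 ± 51.6 and 518 ± 63.4 CPM at 0, 5 and 12 h and did not pass (adjusted p = 0.215 at 5 h).

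**Figure D1:**
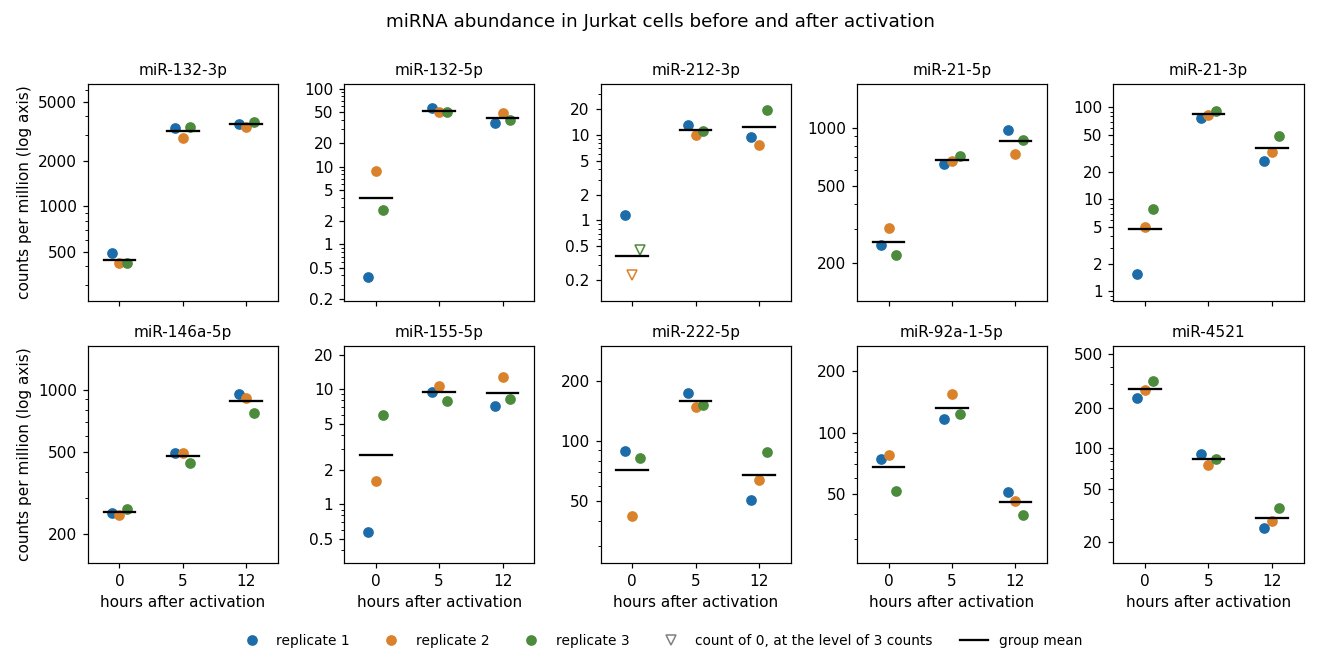
Abundance in CPM on a log axis at 0, 5 and 12 h after activation for 10 miRNAs, with 1 point per replicate library and a black line at the mean of the 3 replicates. Open triangles are counts of 0 drawn at the level of 3 counts. miR-132-3p went from a mean of 442 at 0 h to 3192 at 5 h and 3532 at 12 h, whereas miR-4521 went from 275 to 83.2 and 30.2.

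The second comparison asked which miRNAs differed from the unactivated cells at 12 h. miR-132-3p was at 3532 ± 136 CPM, 7.99-fold above 0 h (log2 change 3.00, SE 0.12, n = 3, edgeR adjusted p = 1.48e-12). miR-146a-5p rose 3.46-fold to 882 ± 95.5 CPM (log2 change 1.79, SE 0.13, adjusted p = 1.1e-08) and miR-21-5p 3.34-fold to 854 ± 123 CPM (log2 change 1.74, SE 0.15, adjusted p = 1.07e-07). miR-21-3p rose to 36.1 ± 11.6 CPM (log2 change 2.96, SE 0.41, adjusted p = 0.00015). miR-4521 fell to 30.2 ± 5.48 CPM (log2 change -3.19, SE 0.20, adjusted p = 1.28e-09), and was lower in each of the 3 libraries at 12 h than in each control.

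miR-132-5p rose to 41.8 ± 6.77 CPM (log2 change 3.37, SE 0.60, adjusted p = 0.00224) and miR-212-3p to 12.2 ± 6.45 CPM (log2 change 4.75, SE 0.90, adjusted p = 0.00452). miR-212-5p reached 6.31 ± 3.24 CPM, at least 74.0-fold above the level of 3 counts over the controls (adjusted p = 0.00104), a limit that was 41.3-fold and 46.5-fold without replicate 1 and 2 of 0 h. The miR-132-5p change was 4.89 without replicate 2 of 0 h and 4.50 with limma-voom. Its call was lost with only the 0 h and 12 h libraries in the fit (adjusted p = 0.0877), without the 2 shallowest libraries (0.0776) and on the deposited log2 values (0.0810). The fitted miR-212-3p change was 10.06 without replicate 1 of 0 h, where the controls held 0 counts, and 4.14 without replicate 2 of 0 h. Its call was lost without replicate 3 of 12 h (adjusted p = 0.0588), without the 2 shallowest libraries (0.108) and with only the 2 groups in the fit (0.110). Where these calls were lost, the log2 change was 3.22 to 4.15 for miR-132-5p and 3.81 to 4.76 for miR-212-3p.

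A pair of miRNAs fell at 12 h by less than miR-4521. miR-296-3p went from 114 ± 1.01 to 64.6 ± 1.19 CPM (log2 change -0.82, SE 0.18, adjusted p = 0.0148). miR-25-5p, the less abundant arm of a member of the miR-106b/miR-25 cluster, went from 76.9 ± 10.6 to 38.7 ± 9.05 CPM (log2 change -0.99, SE 0.22, adjusted p = 0.0210). Both calls were lost with library totals as the only scaling (log2 change -0.78 for miR-296-3p and -0.93 for miR-25-5p, adjusted p = 0.0619 for both) and with upper quartile factors (0.0788 for miR-296-3p and 0.0917 for miR-25-5p), which raised the median log2 change of all tested rows by 0.16. They were also lost with only the 2 groups in the fit (0.0556 and 0.111), without the 2 shallowest libraries (0.0631 and 0.161) and without replicate 1 of 0 h (0.0667 and 0.143). The miR-25-5p call was lost as well without replicate 3 of 0 h (0.0558), without replicate 3 of 12 h (0.0750) and on the deposited log2 values (0.0770). Where the calls were lost, the log2 change was -0.83 to -0.67 for miR-296-3p and -1.03 to -0.79 for miR-25-5p.

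In all, 10 rows passed at 12 h, 7 higher and 3 lower than at 0 h. The split was 7 higher and 1 lower with library totals alone and without replicate 1 of 0 h, and 9 higher and 1 lower with upper quartile factors. With only the 0 h and 12 h libraries in the fit 6 rows passed, and on the deposited log2 values 6. In 85 rows (12.1%) the groups did not overlap, against 10% by chance. The 7 that rose at 12 h were all among the 10 that had risen at 5 h (both comparisons use the same 0 h libraries), and miR-4521 fell at both times.

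miR-142-3p, an abundant miRNA of blood cells, had 7764 ± 293 CPM at 0 h, 9693 ± 306 at 5 h and 10153 ± 755 at 12 h. It did not pass at 12 h (log2 change 0.39, SE 0.10, adjusted p = 0.0647), but did with upper quartile factors (adjusted p = 0.00533), a stricter filter (0.0448), DESeq2 (0.00844), limma-voom (0.0260) and 1 row per mature miRNA (0.0435). miR-222-3p, at 972 ± 65.1 CPM, did not pass at 12 h either (log2 change 0.44, adjusted p = 0.0647), but did with upper quartile factors (0.00533), a stricter filter (0.0279), DESeq2 (0.00282), 1 row per mature miRNA (0.0435) and without replicate 3 of 12 h (0.0484). The opposite arm miR-142-5p had 1467 ± 92.5, 1540 ± 151 and 1402 ± 123 CPM at the 3 times.

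The third comparison, 12 h against 5 h, asked what continued to change after the early response. miR-146a-5p rose further, from 478 ± 31.4 to 882 ± 95.5 CPM (log2 change 0.88, SE 0.13, n = 3, edgeR adjusted p = 0.000349), and miR-4521 fell further, from 83.2 ± 8.06 to 30.2 ± 5.48 CPM (log2 change -1.47, SE 0.19, adjusted p = 0.000224). A pair of less abundant arms fell after their increase at 5 h. The increase and the fall rest on the same 5 h libraries and are not independent results. miR-92a-1-5p went from 132 ± 20.5 to 45.6 ± 5.82 CPM (log2 change -1.53, SE 0.21, adjusted p = 0.000349), and miR-222-5p from 158 ± 14 to 67.7 ± 18.7 CPM (log2 change -1.22, SE 0.25, adjusted p = 0.0248). Against 0 h, neither passed at 12 h (log2 change -0.58, adjusted p = 0.511 for miR-92a-1-5p and -0.08, adjusted p = 0.991 for miR-222-5p).

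The miR-222-5p call between 12 h and 5 h was lost without replicate 1 of 5 h (adjusted p = 0.0636) or replicate 2 of 12 h (0.479), with upper quartile factors (0.0859), with a stricter filter (0.0923) and on the deposited log2 values (0.299), with a log2 change of -1.25 to -1.06 in these settings. miR-21-3p had 84.2 ± 7.19 CPM at 5 h and 36.1 ± 11.6 at 12 h and did not pass (log2 change -1.22, SE 0.37, adjusted p = 0.414). It passed with no filter (adjusted p = 0.00105), limma-voom (0.00398), only the 2 groups in the fit (0.0199), the replicate number as a block (0.000786) and without replicate 1 of 0 h (0.0276). miR-132-3p was 1.11-fold higher at 12 h than at 5 h and miR-21-5p 1.26-fold, and neither passed (adjusted p = 1 and 0.720).

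Between 12 h and 5 h, 4 rows passed, 1 higher and 3 lower at 12 h. The number was 12 with no filter on low counts (8 higher and 4 lower), 11 with the replicate number as a block (7 and 4) and 10 without replicate 1 of 12 h (7 and 3), in each case with the same 4 among them, so that in these settings most of those that passed were higher at 12 h. Without replicate 2 of 5 h it was 2 higher and 3 lower. In 90 rows (12.8%) the groups did not overlap, against 10% by chance. Upper quartile factors raised the median log2 change of all rows between these times by 0.16 and gave 1 higher and 2 lower.

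The test of any difference among the 3 times called 12 miRNAs: both arms of miR-132, miR-212, miR-21 and miR-222, and miR-146a-5p, miR-4521, miR-92a-1-5p and miR-296-3p. miR-132-3p (edgeR adjusted p = 3.87e-12) and miR-4521 (2.76e-09) had the smallest p. miR-25-5p did not pass this test (adjusted p = 0.0592). The number was 21 with no filter, 21 with the replicate number as a block, 7 on the deposited log2 values and 7 without replicate 2 of 12 h.

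Groups of miRNAs were compared next, as lists fixed in advance. Of 14 tested members of the list of miRNAs reported to rise in activated T cells, 8 rose and 0 fell at 5 h (11 rose when adjusted over the list alone). At 12 h, 7 rose and 0 fell (9 adjusted over the list alone). The list passed camera at 5 h (adjusted p = 3.64e-14, and adjusted p = 0.00400 with an estimated correlation) and at 12 h (adjusted p = 1.53e-13, and 0.00524 with an estimated correlation). Members that did not pass included miR-182-5p, with 1184 ± 119, 1466 ± 81.6 and 1331 ± 191 CPM at 0, 5 and 12 h, and miR-210-3p, with 24.4 ± 10.5, 23.1 ± 2.70 and 25.1 ± 2.63 CPM. All 4 arms of the miR-132/miR-212 cluster rose at both times, also when adjusted over the list alone (camera adjusted p = 2.51e-11 at 5 h and 4.22e-10 at 12 h). With an estimated correlation the adjusted p of that cluster was 0.00400 and 0.00559.

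Of 4 arms of the miR-221/miR-222 pair, 2 rose at 5 h, both of miR-222 (4 adjusted over the list alone; camera adjusted p = 0.000581). That call was lost with an adjusted p of 0.0638 with an estimated correlation. At 12 h, 0 of the 4 arms passed with edgeR and limma-voom, 1 with DESeq2 and 2 at an unadjusted p under 0.05 (1 adjusted over the list alone; camera adjusted p = 0.395). Of 8 tested miRNAs linked to NF-kB, 3 rose at both times, miR-132-3p, miR-21-5p and miR-146a-5p, which are also in the T cell list (4 adjusted over the list alone at each time). The NF-kB list passed camera at 5 h (adjusted p = 8.01e-06), which was lost with an adjusted p of 0.217 with an estimated correlation, and at 12 h (adjusted p = 0.0190), which was lost with an adjusted p of 0.790 with an estimated correlation. The 12 h call of this list was also lost with the replicate number as a block (adjusted p = 0.0640) and with no filter (0.104). It was lost without replicate 1 (0.170), 2 (0.166) or 3 of 0 h (0.169), replicate 1 (0.238) or 2 of 5 h (0.202), and replicate 1 (0.483) or 2 of 12 h (0.309). In these fits the 8 tested members of the list entered as repeated precursor rows, 12 rows in the main fit. With 1 row per mature miRNA the list passed at both times (camera adjusted p = 1.31e-06 at 5 h and 0.000200 at 12 h).

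Camera called 4 of 23 lists at 5 h and 3 at 12 h, all of them towards higher values. These lists overlap and are not separate results. The T cell list also holds all 4 arms of the miR-132/miR-212 cluster, and miR-221-3p and miR-222-3p. Between 12 h and 5 h it called 0 lists (smallest adjusted p = 0.276), with 3 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 with fry. Fry, which tests whether the members of a list move 1 way on balance, called 5 lists at 12 h against 0 h. They were the 3 above and, towards lower values, the miR-106b/miR-25 cluster (adjusted p = 0.0177) and the miR-183/miR-96/miR-182 cluster (0.0327). In the miR-183/miR-96/miR-182 cluster edgeR called 0 of 5 tested arms at 12 h and DESeq2 1. Their median log2 change was -0.02 and the lowest -7.75, while their summed abundance was 3447 CPM at 0 h and 3568 at 12 h. A fall of the cluster as a whole is therefore not shown.

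Several groups that are often discussed in T cells showed 0 members past the threshold. Of 13 tested miRNAs reported to fall on T cell activation, edgeR, DESeq2 and limma-voom each called 0 in every comparison, and 0, 0 and 1 had an unadjusted p under 0.05 at 5 h, at 12 h and between these times. Among them, miR-150-5p had 271 ± 9.71, 259 ± 25.9 and 246 ± 14.7 CPM at 0, 5 and 12 h, and miR-29b-3p had 238 ± 50.8, 246 ± 37.7 and 224 ± 26.8 CPM. miR-181a-5p, which sets the sensitivity of the T cell receptor in thymocytes, had 29963 ± 2689, 26374 ± 964 and 32350 ± 8272 CPM. The 9 tested members of the let-7 family had 0 calls in every comparison with the same 3 tools, with 1, 0 and 1 at an unadjusted p under 0.05. The 10 tested arms of the miR-181 family also had 0 calls, with 0, 0 and 1 at an unadjusted p under 0.05.

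In the miR-17/miR-92a cluster, a driver of lymphocyte proliferation, 1 of 11 tested arms rose at 5 h and 1 fell between 5 h and 12 h, in both cases miR-92a-1-5p (1 adjusted over the list alone in each; camera adjusted p = 0.742 and 0.869). Of its main arms, miR-17-5p had 12654 ± 440, 13352 ± 559 and 12403 ± 372 CPM at 0, 5 and 12 h. miR-92a-3p, on its precursor on chromosome 13, had 308 ± 57.4, 383 ± 50.9 and 356 ± 26.5 CPM. In the miR-106b/miR-25 cluster 1 of 6 arms, miR-25-5p, fell at 12 h (1 adjusted over the list alone; camera adjusted p = 0.554). Markers of other cell types made 5 lists with 16 tested members, of which edgeR, DESeq2 and limma-voom called 0 in every comparison (2, 1 and 2 at an unadjusted p under 0.05). Adjusted over each list alone, 1, 0 and 0 passed with edgeR: miR-122-5p at 5 h (adjusted p = 0.0404), which had 66.8 CPM in replicate 3 of 5 h and 9.03 or less in the other libraries. Of the markers, miR-223-3p, a miRNA of myeloid cells, had 120 ± 13, 133 ± 11.7 and 149 ± 7.74 CPM, and miR-451a, of red blood cells, had 6.11 ± 2.38, 6.24 ± 3.06 and 4.72 ± 3.07 CPM. Among entries that match structured RNAs, 3 were tested and 0 called by the 3 tools at any time (0, 0 and 1 at an unadjusted p under 0.05).

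Across the 701 tested rows the changes at 5 h and at 12 h had a Pearson correlation of 0.613 and a Spearman correlation of 0.474, where rows are not independent replicates. Both changes share the same 0 h libraries: 100 simulations of unchanged groups gave a mean Pearson correlation of 0.501 (0.316 to 0.617) and a mean Spearman correlation of 0.435, so the measured Pearson value lay within the simulated range. The covariance was 1.49, against 1.10 (0.597 to 1.43) in the simulations. For the 139 rows with a mean of at least 100 CPM the Pearson correlation was 0.820, against 0.494 (0.344 to 0.664) for the same rows in the simulations. It was 0.395 for all rows without replicate 3 of 5 h.

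**Figure D2:**
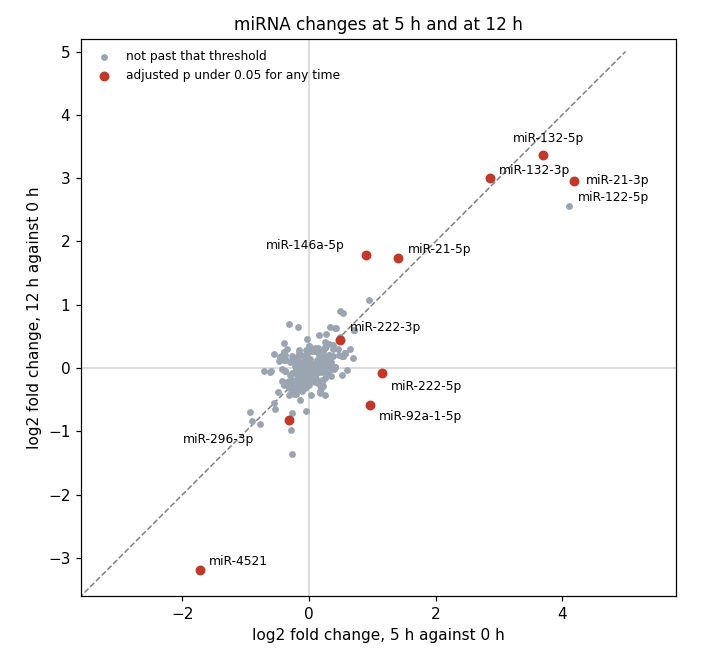
Log2 fold change at 5 h against 0 h (horizontal) and at 12 h against 0 h (vertical) for the 283 tested rows with a mean of at least 10 CPM, with 1 point per row and a dashed line of equal change. Red points have an adjusted p under 0.05 for any difference among the 3 times, and both arms of miR-212 lie below the abundance limit and are not drawn. miR-146a-5p and miR-4521 lie farther from 0 at 12 h than at 5 h, and miR-222-5p and miR-92a-1-5p lie at 1.15 and 0.96 at 5 h but at -0.08 and -0.58 at 12 h.

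On GRCh38, the precursors of miR-132 (chromosome 17, 2049908 to 2050008) and miR-212 (2050271 to 2050380) lie 262 bp apart on the minus strand. No annotated protein-coding or long noncoding gene on that strand overlaps them. The miR-21 precursor (chromosome 17, 59841266 to 59841337) overlaps an exon of VMP1, and that of miR-146a (chromosome 5, 160485352 to 160485450) an exon of the long noncoding RNA MIR3142HG. The precursors of miR-222 (chromosome X, 45747015 to 45747124) and miR-221 lie 748 bp apart in an intron of MIR222HG. That of miR-92a-1 (chromosome 13, 91351314 to 91351391) lies in an exon of MIR17HG, and that of miR-25 (chromosome 7, 100093560 to 100093643) in an intron of MCM7. miR-4521 maps to chromosome 17 (8186945 to 8187004), in no annotated protein-coding or long noncoding gene, and tRNA genes were not searched. The miR-296 precursor maps to chromosome 20 (58817615 to 58817694), in an exon of a long noncoding RNA.

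The 2 arms of 161 precursors were compared as ratios, to ask whether arm use changed. With limma 0 ratios passed in any comparison, with 11, 14 and 11 at an unadjusted p under 0.05 for 5 h, 12 h and 12 h against 5 h. On simulated data this test called 28.1% of ratios changed 4-fold, so it would miss most shifts of arm use of that size or smaller.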

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

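In the first pattern below, the tests of other arm ratios and of the miR-17/miR-92a cluster were chosen only after its result was seen, as was the limit of 10 CPM in the second pattern; the fits without single libraries were planned, though the bound they were held to in the first pattern was set afterwards, and the other tests were planned.

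For 4 miRNAs the change against 0 h differed between 5 h and 12 h. As both changes share the 0 h libraries, this is the comparison of 12 h with 5 h given above and no further test. The 12 h change minus the 5 h change on the log2 scale was -1.47 for miR-4521 (edgeR adjusted p = 0.000224) and -1.53 for miR-92a-1-5p (adjusted p = 0.000349). It was 0.88 for miR-146a-5p (adjusted p = 0.000349) and -1.22 for miR-222-5p (adjusted p = 0.0248).

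The first pattern is the fall of a pair of less abundant arms, miR-92a-1-5p and miR-222-5p, between 5 h and 12 h. A general shift of less abundant arms is argued against by the other 53 precursors with a less abundant arm of at least 10 CPM. Their ratio of the less to the more abundant arm changed by a median of -0.11 (95% bootstrap interval -0.23 to 0.06). That interval resamples precursors, so it does not measure the spread between libraries. In 2 of the 53 the ratio fell by more than 1, among them miR-21 (-1.58, limma adjusted p = 0.505). The ratio of miR-92a-2, which has the same more abundant arm as miR-92a-1, changed by -1.004 (SE 0.279, limma adjusted p = 0.282). Against 0 h the miR-92a-2 ratio changed by -0.54 at 5 h (limma adjusted p = 0.707) and by -1.55 at 12 h (adjusted p = 0.0596). A fall shared by the miR-92a-1 and miR-92a-2 precursors was not tested and stays open. The ratios of the precursors of the pair itself, miR-92a-1 (-1.43, limma adjusted p = 0.166) and miR-222 (-1.19, adjusted p = 0.441), did not pass, so a shift relative to the opposite arm is not shown. A single library does not carry the fall of miR-92a-1-5p, which stayed at -1.37 or lower without each of the 6 libraries, and a change of the whole miR-17/miR-92a transcript is argued against by the 2 other less abundant arms of that cluster tested with a mean of at least 10 CPM, miR-17-3p (0.12, SE 0.18) and miR-20a-3p (0.01, SE 0.21), with a median of 0.0668 (-0.21 to 0.34). Below that limit, miR-18a-3p (8.54 CPM) had a log2 change of 0.92 (SE 0.44) and miR-19b-1-5p (0.752 CPM) of -2.26 (SE 2.46), neither past the threshold. For miR-222-5p the change stayed at -1.08 or lower, but its call was lost without replicate 1 of 5 h (adjusted p = 0.0636) or replicate 2 of 12 h (adjusted p = 0.479), so a part played by single libraries stays open. Time after activation may act on the levels of these arms, which is a hypothesis found and tested on the same data. It cannot be told apart from time in culture alone.

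The second pattern is the fall of miR-4521 to 30.2 CPM at 12 h from 275 at 0 h. Scaling does not account for it, since the log2 change was -3.03 or lower under 3 other scalings, nor does a single library, since it was -3.07 or lower without each of the 9. A loss of fragments of structured RNAs in general, by about as much, is argued against by the 2 other such entries with a mean of at least 10 CPM, miR-1246 (log2 change 0.18, SE 0.27, 458 CPM) and miR-4454 (-0.11, SE 0.24, 39.9 CPM), with a median of 0.04 (-0.32 to 0.40). The remaining entry, miR-1260a (-0.22, SE 2.80), had 0.377 CPM and says nothing; the median over all 3 was -0.11. The list held no other tested entry, so a loss limited to some fragments stays open. With a general loss, scaling and a single library argued against, a response of this RNA to activation is a candidate explanation. Such a response cannot be told apart from an effect of time in culture, as no later unactivated cells were sampled. Whether the tRNA gene that miR-4521 is linked to was transcribed or processed differently was not tested.

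The counts of changed miRNAs and lists were set against other splits of the same libraries. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split was the 1 with as many miRNAs for 5 h against 0 h (11, highest other 0), for 12 h against 0 h (10, highest other 2) and for 12 h against 5 h (4, highest other 0). For lists it was the 1 with as many at 5 h (4, highest other 1) and at 12 h (3, highest other 2), while for 12 h against 5 h, with 0 lists, all 10 splits gave as many (highest other 1). For any difference among the 3 times, 100 of the 280 possible splits were drawn, the real one included. Of these, 1, the real one, gave 12 or more miRNAs (highest other 8). Chance is thus unlikely for that count, but with 1 of 100 splits it is not excluded.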

How the results depend on the processing

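The settings with 1 row per mature miRNA and without the 2 shallowest libraries were chosen after the data were seen. Of 25 calls of a named miRNA in a comparison, 295 of 319 values under other settings and 207 of 225 values with 1 library left out stayed past the threshold in the same direction, and 0 reversed. The calls of miR-132-3p, miR-21-5p, miR-21-3p, miR-146a-5p and miR-4521 against 0 h were kept under every setting and left-out library tried, except that miR-146a-5p at 5 h (0.90) lies under the alternative minimum log2 change of 1; those lost are given with their values in the results above. Of 1424 values for the 65 uncalled pairs, 19 passed. The numbers of changed miRNAs at 5 h, at 12 h, at 12 h against 5 h and at any time were 11, 12, 4 and 12 with 1 row per mature miRNA, 12, 7, 4 and 8 without the 2 shallowest libraries, 12, 13, 4 and 14 with DESeq2, and 10, 11, 5 and 11 with limma-voom. No filter on low counts, which adds rows near 0, gave 17 at 5 h (10 higher and 7 lower, against 10 and 1), 12 for 12 h against 5 h (8 higher and 4 lower, against 1 and 3) and 21 at any time. Limma on the deposited log2 values, which differs in the rows, the scaling and the test at once, gave 5 at 5 h, 6 at 12 h and 7 at any time. Which of these lowers the numbers was not tested. Fitting only 0 h and 12 h gave 6. The replicate number as a block gave 11 for 12 h against 5 h (7 higher and 4 lower) and 21 at any time, where the cause was not tested. Whether the replicate numbers pair the libraries stays open. Over all tested rows, deviations from the group means correlated by only -0.0297 to 0.0604 between libraries of the same number. Of 9 libraries, 5 correlated best, among the 6 libraries of other times, with 1 of the 2 of their own number. That count was not tested against chance. With 1 library left out the number was 3 to 10 for 12 h against 5 h (10 without replicate 1 of 12 h, 7 higher and 3 lower) and 7 to 15 at any time (7 without replicate 2 of 12 h). At 12 h the split of 7 higher and 3 lower was 7 and 1 with library totals and 9 and 1 with upper quartile factors. Lists called at 5 h were 2 with an estimated correlation and at 12 h 5 with fry. The correlation of the changes was 0.820 for rows of at least 100 CPM (0.494 for these rows in simulated unchanged groups, which share the 0 h libraries as well) and 0.395 to 0.713 with 1 library left out. In simulated data with many more changed rows than were called here, edgeR recovered all 2-fold changes of rows with at least 100 CPM. Limma-voom recovered 94.1% of these at 5 h. Of all rows changed 2-fold, edgeR recovered 36.8% and 29.8% at 5 h and 12 h, so depth and spread limit what can be said of miRNAs with low counts.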

Other observations

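The values of miR-122-5p, miR-9-3p, miR-9-5p and miR-93-5p given here were chosen only after they were seen, and none was used as a test of an explanation.

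Jurkat cells held appreciable amounts of miR-9, a miRNA known best from neural cells. miR-9-3p had 609 ± 59.0 CPM at 0 h, 591 ± 75.1 at 5 h and 562 ± 55.9 at 12 h (SD, n = 3), and miR-9-5p had 144 ± 16.4, 192 ± 6.70 and 145 ± 39.2 CPM. The miR-9-5p change at 5 h was 0.41 on the log2 scale (SE 0.18, edgeR adjusted p = 0.695). Other abundant miRNAs of the miR-17 family that did not pass included miR-93-5p, with 18992 ± 3157, 14544 ± 548 and 18331 ± 4732 CPM (log2 change -0.38 at 5 h, SE 0.15, adjusted p = 0.668).

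Clusters that are typical of other tissues were almost silent. Of 32 listed miRNAs of the imprinted 14q32 cluster 1 was tested, and of 22 listed miRNAs of the placental and stem cell clusters 0 had enough counts.

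miR-122-5p, the main miRNA of liver, was not even across libraries. Its counts in replicates 1, 2 and 3 were 0, 27 and 14 at 0 h, 22, 2 and 1139 at 5 h, and 118, 107 and 38 at 12 h. Replicate 3 of 5 h thus held 66.8 CPM and the other libraries 9.03 or less. It did not pass in edgeR at 5 h (adjusted p = 0.253, or 0.0404 when adjusted over its list of markers alone).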
